A study of Mus musculus with 4 samples.

How the data were processed

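RNA of mouse CD8+ T cells from spleens and lymph nodes, activated in culture, was sequenced as 4 polyadenylated libraries, 2 labelled WT and 2 labelled Irf8 knockout. Groups and replicate numbers were taken from the sample titles and genotype labels and from nothing else. Per the submitters' processing notes, Trim Galore 0.4.4, HISAT2 2.2.1, StringTie 2.1.4 and DESeq2 were used with the mm10 build. Their settings, the DESeq2 version, the gene annotation and the use of strand are not given in the sources used here. The authors deposited a table of 49490 genes, of which 22331 were at 0 in all 4 libraries. It holds 1 column of normalized counts per library, a signal that is not whole-numbered, per the file headers and the values. The authors' table also holds a mean, a log2 fold change with its standard error, a Wald score (the fold change divided by its error), and a p-value with its adjusted p-value, deposited under DESeq2's column names. The sign of the deposited log2 values is that of WT over knockout, and it was turned around where it was compared. Spreadsheet conversion had turned 24 gene names into dates, and those genes were left unnamed.

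The values in each column were whole multiples of 1 smallest step, within a tolerance of 0.01 reads for 100.0% of values, so the reads per gene could be recovered. Recovered totals were 58899365 and 59724952 reads for the libraries labelled WT and 59091255 and 59489280 for those labelled knockout, with size factors of 0.983, 0.979, 1.02 and 1.03. At this depth a gene with 0 reads could hold up to 3 reads per library at a 95% level, which was used as the floor for every bound on a fold. Such bounds cover counting error only, since polymerase copies of a fragment cannot be told from separate molecules. Each library was counted as a replicate because the labels number them so. The libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 23.6 for the pair labelled WT and 6.75 for the pair labelled knockout, as technical repeats prepared separately would too. Coordinates, strand and transcript length came from the GENCODE M21 annotation of GRCm38, the same assembly as mm10, matched by exact symbol. It held 95.2% of the table's names once, and 96.4% of the genes tested.

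The design written before the data were examined called for edgeR on counts and, for a table of normalized values alone, for limma. The table held normalized values, so the main test was limma (eBayes with trend and robust variance) on log2(normalized count + 1), with genes kept at a value of at least 10 in at least 2 libraries. That left 18378 genes. Fold changes on this scale can understate the change of genes with low values. They can overstate it where 1 library of a group has no reads. Folds in the text are ratios of group means. No covariate was fitted. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 32 lists, beside camera with an estimated correlation and fry. The lists covered T cell identity, effector and inhibitory molecules, transcription factors, cytokines and receptors, interferon responses, cell cycle, metabolism, stress responses, ribosomal, histone and mitochondrial transcripts, neighbours of Irf8, and markers of other cells of spleen and lymph node. Another 6 lists were written after the data had been examined. They hold genes of plasmacytoid dendritic cells, conventional dendritic cells, B cells, macrophages, neutrophils and sex chromosomes.

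Genes were named by a rule fixed before the data were examined. It took Irf8, then the 10 largest increases and 10 largest decreases among genes past the threshold whose groups did not overlap and whose higher group had a mean of at least 100, leaving out predicted models, antigen receptor segments and sex-linked genes. It then took from each list up to 2 members that rose and 2 that fell with the smallest adjusted p. The results of some genes taken by this rule are not reported here. Alternatives fixed beforehand were median centring, pseudocounts of 0.1 and 10, no filter or a minimum of 50, an added threshold of 1 on the log2 scale, a replicate block, leaving out each library, and other tools. These tools were DESeq2, limma-voom, and edgeR with other factors, without robust variance or with glmTreat against 1.2-fold, all on the recovered reads. edgeR with TMM factors on the recovered reads and limma without robust variance were added after the data had been examined.

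The tests were tried on simulated counts drawn for the real genes with known changes in 200 genes. For the knockout against WT comparison, over 17492 simulated genes tested, limma recovered 53.7% of 1.5-fold, 79.1% of 2-fold and 98.5% of 4-fold changes. Of its calls, 8.30% were false, a larger share than the adjusted p threshold aims at. The real comparison called 6131 genes, with 1209 higher and 32 lower by more than 4-fold. The simulation held far fewer changed genes, so its rates need not carry over to the real calls. Its changed genes were drawn only from genes with higher counts than the filter asked for, so recovery at low counts was not measured. Work was done with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.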

Results

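The series measured polyadenylated RNA of mouse CD8+ T cells, the cytotoxic lineage of T lymphocytes, taken from spleens and lymph nodes and activated in culture. The 4 libraries fell into 2 genotype groups of 2 libraries each, a WT group carrying an Irf8 allele flanked by recombination sites and an Irf8 knockout group. Irf8 encodes interferon regulatory factor 8, a transcription factor of immune cells best known for its part in the development of dendritic cells and other myeloid cells. The libraries held 58899365 and 59724952 reads in the WT group and 59091255 and 59489280 reads in the knockout group. The 10 most abundant genes took 7.70% and 7.99% of the reads in the WT libraries and 6.30% and 6.18% in the knockout libraries. Ccl5, a chemokine of effector T cells, was the most abundant gene in each of the 4 libraries. Across genes, the Spearman correlation was 0.9904 between the WT libraries, 0.9925 between the knockout libraries, and 0.9451 to 0.9465 between groups, where genes are not independent replicates. Principal component 1 held 80.6% of the variance. The labels do not say that the libraries of a group came from separate animals or cultures, so every p below measures only the spread between these libraries, which may be technical.

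The study compared the genotypes to find the genes that IRF8 regulates in activated CD8+ T cells, and the targeted gene was read first. Irf8 (ENSMUSG00000041515.10, chromosome 8, 120736358 to 120756694, plus strand, mm10) had normalized counts of 6364 and 6081 in the WT libraries against 89508 and 90222 in the knockout libraries. The group means were 6222 ± 200 (SD, n = 2) and 89865 ± 505 (SD, n = 2). Irf8 was thus 14.4-fold higher in the libraries labelled knockout, with a log2 fold change of 3.85, a standard error of 0.04 and an adjusted p of 4.32e-08 by limma. In counts per 1e6 reads, the level was 106 and 99.7 in the WT libraries and 1546 and 1558 in the others. The authors' deposited table gives the same size, -3.85 on the log2 scale for WT over knockout. A genotype that removes an exon can leave reads from the rest of a gene, but the direction found here goes against the labels. The groups are therefore called the libraries labelled WT and the libraries labelled knockout throughout, and every direction below is that of the libraries labelled knockout over the libraries labelled WT.

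**Figure D1:**
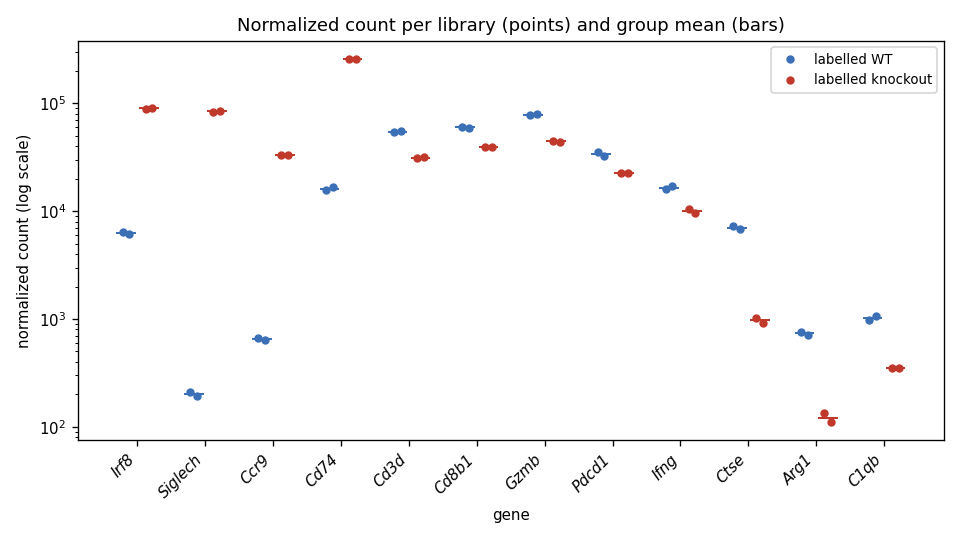
Normalized count on a log axis for 12 genes, with 1 point per library and a bar at the mean of each group (n = 2). Irf8, Siglech, Ccr9 and Cd74 were higher in both libraries labelled knockout (red), and Cd3d, Cd8b1, Gzmb, Pdcd1, Ifng, Ctse, Arg1 and C1qb were lower there.

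The genes with the largest increases included Cacna1e, a calcium channel subunit, which had 0 reads in both libraries labelled WT and a mean of 3555 ± 193 (SD, n = 2) in the libraries labelled knockout, at least 1162-fold higher. Klk1, a kallikrein protease, rose from 8.14 and 3.06 to 16476 and 17344, so that its fold hangs on few reads in the libraries labelled WT. Hs3st1, a heparan sulfate sulfotransferase, rose from 6.11 and 3.06 to 3552 and 3564, so that its fold too hangs on few reads. Cd300c, a receptor of myeloid cells, rose 741-fold, from 10.2 and 9.19 in the libraries labelled WT. Gria3, a glutamate receptor subunit, had 7.12 and 0 in the libraries labelled WT against 1651 and 1645, and no fold is given because replicate 1 alone held its WT reads. Pnck was at least 405-fold higher, Nxpe1-ps at least 260-fold, Foxr1 at least 214-fold and Mn1 at least 183-fold, each with 0 reads in the libraries labelled WT. Among the decreases, the pseudogene Serpina3e-ps went from 165 ± 15.5 (SD, n = 2) to 0 reads and was at least 56.2-fold lower. Ccl24, a chemokine of macrophages, fell by 2.98 on the log2 scale, Ctse, the protease cathepsin E, by 2.86 (from 7054 ± 310 to 973 ± 72.9, SD, n = 2 each), Cbr2 by 2.76 and Pf4, a platelet chemokine, by 2.72. Arg1, the arginase of macrophages, had a log2 fold change of -2.59, C3ar1 of -1.90 and Cpm of -1.83. Ccl7 (-2.48) had 323 and 312 in the libraries labelled WT against 97.0 and 32.1, and Rpph1 (-1.99) had 73.3 and 260 against 38.2 and 30.2, so 1 library moves the size of each. The limma adjusted p of these genes lay between 2.41e-07 (Cd300c) and 0.0401 (Rpph1). Bounds for genes with 0 reads rest on a floor of 3 reads per library and cover counting error only, as Serpina3e-ps and Nxpe1-ps do with the added limit that reads of a pseudogene can be shared with its paralogs.

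Of 18378 genes tested, 3662 were higher and 2469 lower in the libraries labelled knockout at an adjusted p under 0.05 by limma, together 33.4% of the genes. The increases were larger: 1932 genes rose and 161 fell by more than 2-fold, 1209 rose and 32 fell by more than 4-fold, and 583 rose and 4 fell by more than 16-fold. Genes that rose more than 4-fold took 0.42% and 0.40% of the reads in the libraries labelled WT and 5.06% and 5.08% in the libraries labelled knockout. In 68.8% of the genes the values of the groups did not overlap, where chance gives 33.3%. The authors' deposited table holds 3343 genes higher and 2188 lower in the knockout columns, and 5319 genes were called in the same direction there and here, 0 in opposite directions. edgeR on the recovered reads called 3702 genes higher and 2658 lower. Centring each library on its median moved the median of all genes from 0.02 to -0.28 and the counts to 2389 higher and 7210 lower, so that 24.9% of calls were higher in place of 59.7%, and edgeR with upper-quartile factors gave 47.1% (3260 higher and 3666 lower). Without knockout-labelled replicate 1 the counts were 1358 higher and 694 lower, and without knockout-labelled replicate 2 they were 1309 higher and 630 lower. An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333, so single genes have no such test here.

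**Figure D2:**
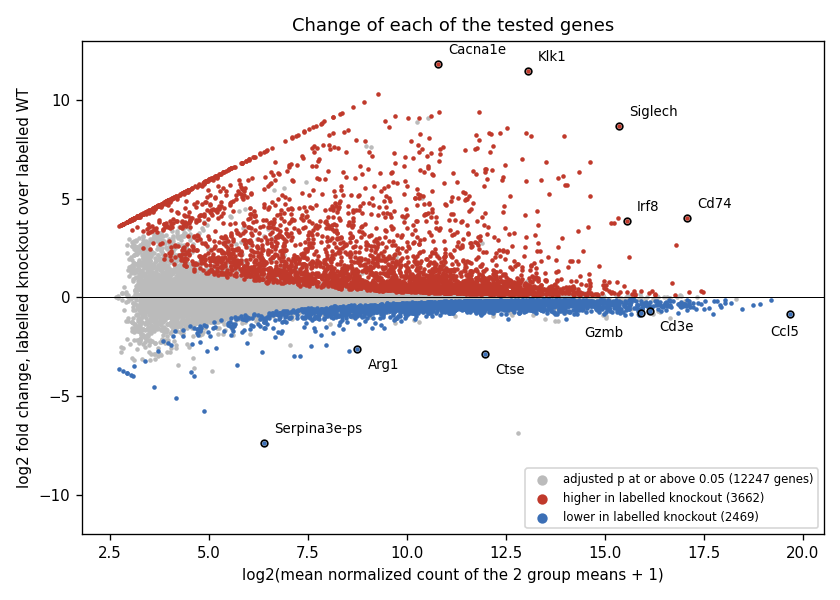
Log2 fold change (libraries labelled knockout over libraries labelled WT) against the log2 mean normalized count for the 18378 tested genes, with 3662 higher genes in red and 2469 lower genes in blue by limma (adjusted p under 0.05). Increases reach far above 4 on the log2 scale, while most decreases lie between 0 and -1.

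Genes of dendritic and myeloid cells were among the most abundant that rose. Siglech, a receptor of plasmacytoid dendritic cells, rose from 202 ± 11.1 to 84289 ± 168 (SD, n = 2 each), or 418-fold. H2-Aa, a class II antigen presentation gene, rose 16.5-fold, Tyrobp, a signalling adaptor of myeloid and NK cells, 35.0-fold, and Cd74, the class II invariant chain, from 16197 ± 690 to 259254 ± 643 (SD, n = 2 each). Of 34 measured myeloid and dendritic cell markers, 20 rose and 8 fell (21 and 8 adjusted over the list alone), with a median of 2.15, and also 2.15 with Mpo and Elane, at 0 reads in the libraries labelled WT, at their bounds. Among those that fell were C1qb, a complement gene of macrophages, from 1022 ± 70.2 to 353 ± 0.265 (SD, n = 2 each), and Ly6c2, which activated T cells also express, by 0.59 on the log2 scale. Limma's camera placed the list above other genes (adjusted p = 6.44e-04, and adjusted p = 0.322 with an estimated correlation). Of 18 measured B cell markers, 12 rose and 0 fell (12 and 0 adjusted over the list alone), led by Cd74 and by Ighm, the heavy chain of immunoglobulin M, which rose from 7419 ± 256 to 37077 ± 106 (SD, n = 2 each). The median of that list was 2.90, or 2.81 with Ebf1, which had 0 reads in the libraries labelled WT, at its bound (camera adjusted p = 4.28e-06, and adjusted p = 0.264 with an estimated correlation). Cd79a, Cd22 and Ms4a1, markers restricted to B cells, did not pass, with log2 fold changes of 0.20, 0.04 and 1.53. Ms4a1 had 0 and 18.4 in the libraries labelled WT against 10.8 and 12.7, so its change hangs on 1 library. Cd79a too had low values, 40.7 and 27.6 against 22.5 and 66.2.

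T cell identity genes were lower in the libraries labelled knockout by similar amounts. Cd3d, a subunit of the CD3 complex, fell from 54583 ± 1172 to 31237 ± 552 and Cd3g from 56311 ± 890 to 33374 ± 660 (SD, n = 2 each). Of 23 measured genes, 0 rose and 21 fell (0 and 22 adjusted over the list alone), and Ptprc and Trat1 had log2 fold changes of -0.08 and -0.32. The median was -0.61, and 65.4% of the level in the libraries labelled WT remained (camera adjusted p = 1.01e-10, and adjusted p = 0.329 with an estimated correlation). The median lay between -0.61 and -0.91 under the deposited scaling and 4 others. Most cytotoxic effector molecules fell too: of 21 measured, 17 fell and 3 rose (18 and 3 adjusted over the list alone), with a median of -0.67, the same with Gzmg at its bound. Gzmc, Gzmf and Gzmd fell further, by 1.54, 1.33 and 1.02 on the log2 scale, while 9 of the 21 lay above the T cell identity median. Gzmb, the protease granzyme B, fell from 78633 ± 981 to 44651 ± 581 and Prf1, the pore-forming perforin, from 29662 ± 376 to 17474 ± 86.2 (SD, n = 2 each). The members that rose were Ctsc, a protease that activates granzymes, by 0.53, Gzmg, with 0 reads in the libraries labelled WT and at least 4.95-fold higher, and Lamp1, a lysosomal protein, by 0.29, a sign that turned to -0.01 with median centring. Camera gave the cytotoxic list an adjusted p of 4.28e-06 (adjusted p = 0.264 with an estimated correlation).

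Of 20 measured inhibitory receptors, 12 fell and 7 rose (12 and 7 adjusted over the list alone). Ctla4, a coinhibitory receptor, fell from 21471 ± 615 to 13291 ± 165 (SD, n = 2 each) and Klrc1, which encodes NKG2A, by 0.66 on the log2 scale. Cd200 rose 5.65-fold and Btla, a receptor of T cells and dendritic cells, 4.28-fold. The median was -0.34, the mean 0.09, and camera did not place the list apart from other genes (adjusted p = 0.108). Of 21 exhaustion and effector transcription factors, 13 fell and 5 rose (14 and 5 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 0.0154, and adjusted p = 0.341 with an estimated correlation). Id2 fell from 72073 ± 2094 to 44318 ± 964 (SD, n = 2 each) and Bhlhe40 by 0.39 on the log2 scale. Runx2 rose 2.43-fold and Zeb2 2.22-fold, and both are transcription factors of plasmacytoid dendritic cells as well as of T cells. The other members that rose were Stat5a, Ikzf2 and Tox2, by 0.47, 0.92 and 0.90.

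Among 30 naive, memory and progenitor genes, 16 rose and 8 fell (17 and 9 adjusted over the list alone), and the median was 0.20, or -0.10 with median centring. Ccr7, a chemokine receptor that guides T cells into lymph nodes, rose 1.76-fold, from 8476 ± 296 to 14923 ± 280 (SD, n = 2 each). Ltb fell by 0.66 and Cd28 by 0.55 on the log2 scale. Camera did not call the list (adjusted p = 0.473). Of the 8 other interferon regulatory factors, Irf5, Irf1 and Irf7 rose, by 1.35, 0.57 and 0.23, and Irf2 fell by 0.25 (5 higher and 1 lower adjusted over the list alone). Their median was 0.23, or -0.08 with median centring (camera adjusted p = 0.167). Of 23 BATF, AP-1 and early activation factors, 5 rose and 10 fell (5 and 10 adjusted over the list alone). Jun, Fos, Batf3, Rel and Nfkb1 rose, by 0.75, 0.33, 1.98, 0.55 and 0.66, while Junb fell by 0.48 and Myc by 0.39. That list had a median of -0.17 and a mean of 0.04 and was not called (camera adjusted p = 0.179).

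Of 21 measured cytokines and chemokines of T cells, 11 fell and 4 rose (12 and 4 adjusted over the list alone). Ifng, the cytokine interferon gamma, fell from 16559 ± 709 to 10010 ± 660 (SD, n = 2 each) and Csf1 by 0.59 on the log2 scale. Ccl22, a chemokine of dendritic cells, rose 8.22-fold and Osm 2.36-fold, and Lif and Il17f rose by 2.41 and 1.24 on the log2 scale. The median was -0.41, the mean 0.01, and camera called the list lower (adjusted p = 0.0285, adjusted p = 0.425 with an estimated correlation, and 0.0623 without knockout-labelled replicate 2). Among 26 cytokine receptors, 10 rose and 12 fell (11 and 13 adjusted over the list alone). Lifr rose 313-fold from 28.5 ± 4.26 to 8930 ± 7.87 (SD, n = 2 each) and Csf2rb2, whose reads can be shared with its paralog Csf2rb, 130-fold. Ifngr1 and Il2rb fell by 0.56 and 0.55. The median was -0.10, the mean 1.07, and camera pointed down without a call (adjusted p = 0.914). Of 33 chemokine receptors, integrins and homing molecules, 11 rose and 15 fell (11 and 15 adjusted over the list alone). Ccr9, a homing receptor of plasmacytoid dendritic cells and gut T cells, rose 51.0-fold to 33235 ± 487 (SD, n = 2) and Cd44 1.46-fold, while Cxcr6 fell by 0.86 and Cxcr3 by 0.57. The median of 0.10 became -0.21 with median centring, and camera pointed down without a call (adjusted p = 0.739). Its sign also turned without WT-labelled replicate 1 (-0.04) or 2 (-0.02), and it was 0.05 and 0.02 without knockout-labelled replicates 1 and 2. Of 22 members of the TNF receptor and costimulatory family, 10 fell and Tnfsf9 alone rose, by 0.68 (11 and 3 adjusted over the list alone). Cd6 fell by 0.85 and Icos by 0.69, with a list median of -0.22 (camera adjusted p = 0.00985, adjusted p = 0.425 with an estimated correlation, and 0.0525 without knockout-labelled replicate 2).

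Type I interferon-stimulated genes fell in 32 of 50 measured members and rose in 6 (32 and 8 adjusted over the list alone). Ifi208 fell from 8220 ± 26.1 to 3821 ± 30.5 (SD, n = 2 each), and Ly6c2 had the next smallest adjusted p among the members that fell. Bst2, a tetherin that is also a surface marker of plasmacytoid dendritic cells, rose 3.63-fold and Stat2 2.51-fold. The median was -0.34 (camera adjusted p = 4.10e-06, and adjusted p = 0.264 with an estimated correlation). It lay 0.271 above the T cell identity median, as did 40 of the 50 members, so the list fell less than the T cell genes. Of 39 genes of interferon gamma induced GTPases and antigen presentation, 21 fell and 5 rose (23 and 6 adjusted over the list alone). Gbp7 fell by 0.56 and Nlrc5, the activator of class I genes, by 0.41. Ciita, the activator of class II genes, rose 18.5-fold, H2-T23 1.51-fold, and Iigp1, Cxcl9 and Tapbp rose by 2.32, 2.28 and 0.28 on the log2 scale. The median was -0.17 and the mean 0.04 (camera adjusted p = 0.00516, and adjusted p = 0.341 with an estimated correlation). Both lists moved beside the dendritic genes above, of which Siglech rose 418-fold, and several of their members belong to families of near-identical genes whose reads can be split.

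Cholesterol synthesis genes rose in 21 of 24 members and fell in 0 (21 and 0 adjusted over the list alone). Fdps, an enzyme of the mevalonate pathway, rose 4.97-fold from 1380 ± 27.7 to 6861 ± 483 (SD, n = 2 each). Stard4 and Ebp had log2 fold changes of 0.03 and -0.01. The median was 1.35 (camera adjusted p = 6.55e-10, and adjusted p = 0.264 with an estimated correlation). Of 18 unfolded protein response genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone), with Herpud1 3.35-fold higher and Xbp1, a transcription factor of secretory cells, 2.84-fold higher. The median was 0.30, and 0.003 with median centring (camera adjusted p = 2.33e-04, and adjusted p = 0.421 with an estimated correlation). In the same libraries Siglech and Tyrobp, genes of dendritic and myeloid cells, were 418-fold and 35.0-fold higher. Of 19 amino acid stress genes, 8 rose and Psph and Ddit3 fell, by 0.27 and 0.28 (9 and 2 adjusted over the list alone). Slc7a5, an amino acid transporter, rose 2.95-fold and Sesn2 2.64-fold. The median of 0.27 became -0.03 with median centring and 0.12 to 0.20 with any 1 library left out, and camera made no call (adjusted p = 0.094). Of 14 heat shock genes, Hspa8, Dnaja1, Dnajb1 and Bag3 fell, by 0.29, 0.28, 0.19 and 0.20, and Hsp90aa1 rose by 0.19, which became -0.11 with median centring (1 and 4 adjusted over the list alone, median -0.10, camera adjusted p = 0.158).

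Glycolysis genes fell in 10 of 23 members and rose in 3 (10 and 3 adjusted over the list alone). Gapdh fell from 110455 ± 2661 to 96141 ± 1004 (SD, n = 2 each) and Eno1 by 0.33 on the log2 scale, while Pfkfb4 rose 4.99-fold, Aldoc 2.68-fold and Pfkl by 0.15. The median was -0.10 and the mean 0.04 (camera adjusted p = 0.0402, and adjusted p = 0.532 with an estimated correlation). The call was lost without WT-labelled replicate 1 (adjusted p = 0.123) and without knockout-labelled replicate 1 (adjusted p = 0.124). Of 61 nuclear genes of oxidative phosphorylation, 14 fell and Ndufs8 rose, by 0.22, which became -0.08 with median centring (13 and 0 adjusted over the list alone). Uqcrh fell by 0.42 and Atp5h by 0.29, and the median was -0.17 (camera adjusted p = 8.50e-05, and adjusted p = 0.532 with an estimated correlation). Across genes, log2 fold changes rose weakly with transcript length (Spearman 0.135), with a trend of -0.142 at 500 bases and 0.045 at 4000 bases. For short transcripts that trend alone is near the size of this list's median, and the list was not tested with it removed. WT-labelled replicate 2 stood apart in many members, such as Ndufa1 (3648 and 6898 in the libraries labelled WT) and Cox7c (7244 and 11449), and without it the median was -0.11, against -0.23 without WT-labelled replicate 1. Of 20 hypoxia response genes, 6 rose and Bnip3l, Higd1a and Rora fell, by 0.31, 0.57 and 0.32 (6 and 4 adjusted over the list alone). Egln3 rose 2.02-fold, and Adm, with 0 reads in the libraries labelled WT, was at least 32.5-fold higher. The median was -0.06, the mean 0.44, and camera pointed up without a call (adjusted p = 0.965).

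The medians of the cell cycle lists lay between -0.04 and 0.08, while single members moved in both directions. The G1/S and G2/M medians lay 0.663 and 0.572 above the T cell identity median, as did all 40 and all 44 of their members. Of 40 genes of G1/S and DNA replication, 8 rose and 5 fell (8 and 5 adjusted over the list alone), with E2f1 1.80-fold and Ung 1.64-fold higher and Cdt1, Pcna, Dut, Pola1 and Mcm6 lower by 0.35, 0.26, 0.33, 0.40 and 0.18 on the log2 scale. The median was 0.05, or -0.25 with median centring (camera adjusted p = 0.965). Of 44 genes of G2/M and mitosis, Cdc25b, Racgap1 and Cenpa fell, by 0.35, 0.20 and 0.24, and Tacc3 rose by 0.27, which became -0.03 with median centring (0 higher and 1 lower adjusted over the list alone). The median was -0.04 (camera adjusted p = 0.291). Of 22 cell cycle inhibitors and p53 targets, Pmaip1, Sesn2, Cdkn2d, Cdkn1a and Phlda3 rose, by 1.05, 1.40, 0.81, 0.62 and 0.51, and Btg2 fell by 0.09 (5 and 1 adjusted over the list alone). The median of 0.08 became -0.22 with median centring (camera adjusted p = 0.206).

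Cytosolic ribosomal protein genes fell in 62 of 76 members (64 lower and 2 higher adjusted over the list alone). Rpl13a fell from 238231 ± 628 to 166074 ± 808 and Rps3 from 148860 ± 1963 to 110347 ± 439 (SD, n = 2 each), and Rpl10 alone rose, by 0.11, which became -0.19 with median centring. These genes have many processed copies whose reads can be shared. The median was -0.42 (camera adjusted p = 2.45e-16, and adjusted p = 0.341 with an estimated correlation), and -0.362 with the trend on transcript length removed. Of 41 replication-dependent histone genes, Hist1h1e, Hist1h2bj, Hist1h4d and Hist1h2ae fell, by 0.55, 0.79, 0.98 and 0.81, and 0 rose (1 lower and 0 higher adjusted over the list alone). The median was -0.55 (camera adjusted p = 1.62e-05, and adjusted p = 0.425 with an estimated correlation), and most of these transcripts lack the poly(A) tail the libraries selected. That median was -0.27 without WT-labelled replicate 2 and -0.70 without WT-labelled replicate 1. Of 13 mitochondrially encoded transcripts, mt-Co1, mt-Nd4, mt-Nd5 and mt-Cytb rose, by 0.33, 0.25, 0.22 and 0.14 (9 higher adjusted over the list alone), and with median centring mt-Nd4 stood at -0.05 and the list median at -0.15 in place of 0.15 (camera adjusted p = 0.213).

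Markers of NK and gamma-delta T cells, of helper T cells, and of blood and stromal cells were not called as lists. Of 22 NK, innate-like and gamma-delta T cell markers, 6 rose and 8 fell (6 and 8 adjusted over the list alone). Tyrobp and Fcer1g, adaptors that myeloid cells share, rose 35.0-fold and 6.68-fold, while Trdc and Il2rb fell by 0.84 and 0.55. The median of 0.10 became -0.20 with median centring (camera pointing down, adjusted p = 0.739). It was -0.22 without WT-labelled replicate 1, -0.08 without knockout-labelled replicate 1, and 0.25 and 0.28 without the replicates 2, so its sign hangs on 1 library. Of 8 CD4, regulatory and helper T cell markers, Cd4 alone rose (1 higher adjusted over the list alone), 63.6-fold from 129 ± 3.30 to 8198 ± 63.8 (SD, n = 2 each). Plasmacytoid dendritic cells of mice express this gene too. The list median of 0.03 became -0.27 with median centring (camera adjusted p = 0.594). Of 15 erythroid, platelet and stromal markers, Cdh5, Pecam1, Col1a1, Cpa3 and Itga2b rose and Pf4 fell (8 and 1 adjusted over the list alone). Cdh5, an endothelial cadherin, rose from 16.3 and 41.9 to 8762 and 8492, Pecam1 rose 2.68-fold, and the other members that rose did so by 1.60, 0.78 and 1.40 on the log2 scale. The median of 0.22 became -0.08 with median centring (camera adjusted p = 0.094, and 0.0256 without WT-labelled replicate 2). Of 12 neighbours of Irf8 on chromosome 8, Slc7a5 and Emc8 rose, by 1.56 and 0.42, and Gse1 and Cox4i1 fell, by 0.43 and 0.19 (2 and 2 adjusted over the list alone). Emc8 and Cox4i1 overlap at their ends, so their reads cannot be told apart there without strand. The median of 0.02 became -0.29 with median centring (camera pointing down, adjusted p = 0.965).

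**Figure D3:**
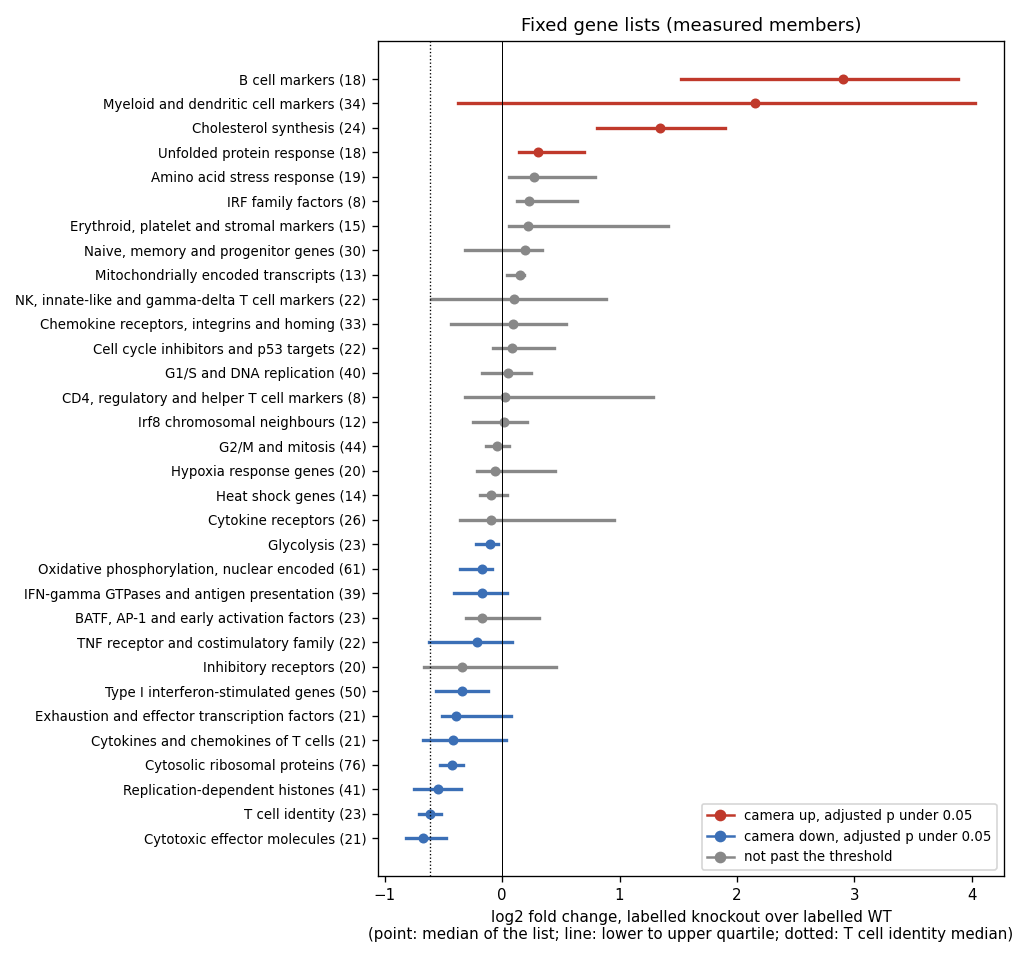
Median log2 fold change (point) and lower to upper quartile (line) of the measured members of 32 gene lists, libraries labelled knockout over libraries labelled WT, with the number of members in parentheses. Lists called higher by camera are red, lists called lower are blue, and the dotted line at -0.61 is the median of the T cell identity list.

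Camera with its preset correlation called 15 of the 32 lists, 11 lower and 4 higher, and the medians of these 15 kept their sign under all 4 other scalings. Of the lists called lower, the cytotoxic list alone had a median below that of the T cell identity list (-0.059 relative to it). The others apart from that list itself lay above it, from 0.067 (histones) to 0.512 (glycolysis), and these differences were not tested. Among lists not called, leaving out 1 library turned the sign of the median for G2/M (-0.042 to 0.001), hypoxia (-0.102 to 0.013) and Irf8 neighbours (-0.040 to 0.066). It moved the median by more than 1.5 times for helper T cell markers (0.090 to 0.163), cytokine receptors (-0.200 to -0.094) and G1/S genes (0.016 to 0.084). With the correlation estimated from these libraries 0 lists were called, the smallest adjusted p being 0.264. Members that the text names only because 5 or fewer of a list passed or missed the threshold were chosen after their values were seen.

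On a scale where the mean of the 23 T cell identity genes is equal in all libraries, limma called 11951 genes higher and 140 lower. Of the 2469 genes that fell under the deposited scaling, 140 were lower and 1230 higher on that scale. It adds about the same amount to every gene, moving the median of all genes to 0.59, so these counts follow from the shift and say nothing more about single genes. This scale was chosen after the data had been examined.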

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

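The added edgeR TMM and limma runs without robust variance were chosen after the data had been examined. Irf8 stayed higher in the libraries labelled knockout under all alternatives, with log2 fold changes from 3.55 (median centring) to 3.89, and from 3.82 to 3.89 with 1 library left out. The counts stayed within 1.5 times 3662 higher and 2469 lower genes except as follows. Median centring gave 2389 and 7210, because it lowers every fold change by the same amount. The added threshold of 1 gave 1932 and 161, and glmTreat 1043 lower genes, because both ask for a larger change. Leaving out 1 library gave 1309 to 4137 higher and 630 to 2759 lower genes. The low values came without knockout-labelled replicate 1 (1358 and 694) and replicate 2 (1309 and 630), which leave the spread to the more variable pair labelled WT, and 2043 and 1933 of the 6131 calls were kept. In these fits the lone library is assumed to vary like the other group, and 0 calls changed sign. Replicate numbers did not pair the libraries (correlation of deviations 0.017 across genes), and a replicate block gave 3415 higher and 2168 lower genes, an Irf8 change of 3.85 and 14 lists called. Named genes were not tallied under the added threshold of 1, where those with smaller changes would fall short by definition. Under the other alternatives, of 2160 values for 120 named genes, 2051 kept direction and side of the threshold, 103 lost the threshold and 6 reversed, all with median centring: Lamp1 -0.0114, Tacc3 -0.0337, Ndufs8 -0.0833, Hsp90aa1 -0.11, mt-Nd4 -0.0536 and Rpl10 -0.19. Lists called numbered 15, against 15 with RLE factors, 13 to 16 with 1 library left out, 0 with an estimated correlation, 26 with directional fry and 31 with mixed fry. The RLE run shifts all genes of the libraries labelled knockout by the same amount, to which camera hardly responds. Fry asks whether a list moves at all, not whether it stands apart from other genes. Directional fry pointed up where camera pointed down for inhibitory receptors (median -0.340), cytokine receptors (-0.097), chemokine receptors, integrins and homing (0.096), NK markers (0.10) and Irf8 neighbours (0.016), and the cause was not tested. At this depth counting error is small beside the spread between libraries, and 2 libraries per group limit the tests.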

Other observations

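All tests reported here were chosen after the results had been seen, except that of the plasmacytoid dendritic cell list, written before its genes' values were seen. Plasmacytoid dendritic cells are the blood and lymphoid cells that sense nucleic acids and secrete type I interferon. Of 16 genes known from them, 15 rose in the libraries labelled knockout by limma, 16 adjusted over the list alone, with a median of 6.02 (camera adjusted p = 6.64e-12, and adjusted p = 0.1003 with an estimated correlation). Tcf4, their lineage factor, went from 478 and 383 normalized counts to 28153 and 28302, Pld4 from 564 and 442 to 40619 and 41104, and Tlr7, a sensor of RNA, from 11.2 and 16.3 to 2651 and 2681. The member that missed the threshold, Klra17, had 0 and 28.6 against 2970 and 2889 (limma adjusted p = 0.0651). In the libraries labelled WT, 9 of the 16 had a mean of at least 100.

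The lists of genes of other cell types moved apart, and the cells themselves were not counted. Of 10 measured neutrophil genes, 9 rose (9 adjusted over the list alone), with a median of 4.02, and also 4.02 with the 3 members at 0 reads at their bounds (camera adjusted p = 1.42e-06, and adjusted p = 0.103 with an estimated correlation). S100a8 went from 47.8 and 90.9 normalized counts to 1224 and 1341. Of 9 conventional dendritic cell genes, 7 rose (8 adjusted over the list alone), with a median of 2.83 (camera adjusted p = 1.55e-04, and adjusted p = 0.132 with an estimated correlation), and Xcr1, a marker of cross-presenting dendritic cells, had a log2 fold change of 0.02. Itgax, another member, stood at 12573 and 12236 in the libraries labelled WT, so this list was not restricted to dendritic cells. Of 8 measured B cell genes listed as not shared with plasmacytoid dendritic cells, Cd83 alone rose (1 adjusted over the list alone, median 0.86, camera adjusted p = 0.224). Its member Cd37 stood at 24218 and 25609 in the libraries labelled WT, so the list was not restricted to B cells. Its median rests partly on Ms4a1, with 0 and 18.4 in the libraries labelled WT against 10.8 and 12.7. Of 16 macrophage genes, 8 fell and Cd163 and Timd4 rose (8 and 3 adjusted over the list alone, median -0.58, mean 0.17, camera adjusted p = 0.145), with C1qa lower by 1.38 and C1qb by 1.53. Of 5 sex-linked genes, the Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y rose and Xist fell (4 and 1 adjusted over the list alone, median 5.53, camera adjusted p = 0.0221, and adjusted p = 0.204 with an estimated correlation). Eif2s3y went from 32.6 and 26.5 to 1276 and 1254, and Xist, which is expressed from the inactive X of females, from 18353 and 17767 to 11724 and 10907. The predicted gene Gm15564, singled out after its values were seen, had 10164 and 10634 in the libraries labelled WT against 0 and 7618 in those labelled knockout.

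Irf8 and dendritic cell genes were higher in the libraries labelled knockout. A gain of these genes in T cells with no change in the amount of T cell RNA is argued against by the T cell identity list, whose median lay 0.631 below that of all genes (-0.631). That fall was known when this explanation was written, and a gain in T cells whose own T cell genes also fell is not addressed by it. RNA of plasmacytoid dendritic cells is a candidate explanation, as 93.8% of their listed genes rose and the most abundant of these reached 40619 and 41104 (Pld4) and 28153 and 28302 (Tcf4), though the labels name CD8+ T cells and some listed genes are also expressed by other cells. For Irf8 itself, swapped genotype labels cannot be told apart from this, since either could leave it higher, as it was by 14.4-fold. Whether a swap would also raise the dendritic cell genes was not tested. Genes of dendritic cells, a possible other source of Irf8 RNA, were higher too, but the origin of the Irf8 reads was not measured. An effect of the genotype in the cells stays open and was not tested.

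T cell genes were lower together in the libraries labelled knockout. The choice of the deposited size factors over 4 other scalings is argued against as the whole cause, since the highest median of the T cell identity list under these was -0.621. All of these scalings rest on the bulk of genes or reads, so an error common to them cannot be excluded. A lower share of T cells with all other cells in constant proportion is argued against too, as the medians of the plasmacytoid dendritic cell and macrophage lists lay 6.60 apart on the log2 scale, more than the sum of their interquartile ranges, 4.10. Dilution of T cell RNA by RNA of the cells whose genes rose cannot be told apart from a common change of these genes within T cells, from the genotype or from activation. The narrow spread of that list (interquartile range 0.193) restates the pattern. Reads in genes more than 4-fold higher rose from 0.42% and 0.40% to 5.06% and 5.08%, while 65.4% of the T cell level remained. That rise is smaller than the loss of T cell RNA. It leaves out RNA of genes that T cells and the other cells both express, so it cannot decide for or against dilution.

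Y-linked genes were higher and Xist lower in the libraries labelled knockout. An origin of all their cells in males is argued against by Xist, which kept 62.7% of its level in the libraries labelled WT. RNA of male cells other than T cells added to RNA of female T cells is a candidate explanation, as the Xist change lay -0.063 from the T cell identity median. T cells pooled from males and females cannot be told apart from this, since all 4 Y-linked genes would rise in both cases and the labels give no sex. These explanations were weighed only by values of the same libraries, and no biological explanation was tested by an experiment.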
